A study of Mus musculus with 14 samples.

How the data were processed

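RNA was measured in splenic B cells of mice, taken by negative selection and cultured for 96 h with LPS at 5 µg/ml and IL-4 at 10 ng/ml, per the labels. Polyadenylated RNA was made into libraries with an Illumina TruSeq mRNA kit. The 14 libraries came from 3 genotypes: wild type (WT, n = 4), mice whose PU.1 gene carries a mutated miR-155 site in its 3' UTR (PU1_KI, n = 5) and mice without miR-155 (miR155_KO, n = 5). The design text calls the replicates biological, with 4 or 5 per genotype, so the spread between libraries of a genotype covers animals and cultures. Index sequences repeat among the libraries in the labels, and which library shared a sequencing pool with which is not given in the sources used here. Pool, culture day and genotype therefore cannot be told apart.

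The authors deposited 1 table of RPKM values (reads per kilobase of gene and per 1e6 reads), with a column per library and a row per gene. Per the submitters' processing notes the steps before it involved Trim Galore and TopHat and the mouse build NCBIM37, with no versions. The read counter, the gene annotation, the strand setting and the kind of reads counted are not given in the sources used here. The table held 22295 rows for 22232 distinct Ensembl genes, with 63 rows that repeat a gene, and 5769 rows were at 0 in every library. All 14 RPKM columns were matched to a library by name, which left 0 unmatched, and none of the 91 pairs of columns was identical. Gene symbols and positions are those of the table; PU.1 appears under its older symbol Sfpi1 and the J chain as Igj. Rows for miR-155 or its host gene, Ighm, Ighg1 and Xist were not used here, and of the constant region genes only Ighg2c was tested. The table held low values for some genes known to be abundant, such as Gapdh, which has many near-identical copies, at 0.982 RPKM in WT, so a single value near 0 need not mean a low level.

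Depth was recovered from the RPKM values, since a gene's RPKM is a whole multiple of what 1 read is worth at that gene's length. In each library the 250 lowest values above 0 among genes spanning under 2500 bp were compared, with the span as the length, and the smallest depth that turned most of them into whole reads was taken. This gave between 31.5 and 52.4 M reads, with M for 1e6, per library. With that depth, between 73.2% and 81.6% of those genes came out within 0.01 reads of a whole number. At this depth 1 RPKM on a 2 kb gene stands for 63.0 to 104.9 reads, so counting error is small for genes past the filter. RPKM sums were left as deposited, and no count model was run on these values.

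Genes with an RPKM of at least 1 in at least 4 libraries were tested, 9627 in all. The test was limma 3.58.1 in R 4.3.3 on log2(RPKM + 0.5), with 1 mean per genotype fitted over all 14 libraries, empirical Bayes moderation with an intensity trend, two-sided, and a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p below is from this test unless another is named. A log2 fold change is on the log2(RPKM + 0.5) scale, which understates the change of low genes. Comparisons were made of PU1_KI against WT, miR155_KO against WT and miR155_KO against PU1_KI. Levels are mean RPKM ± SD and changes are log2 fold change ± SE. Scripts were tested on simulated data with 9627 genes: for PU1_KI against WT a 1.2-fold change was recovered in 26 of 50 genes and changes of 1.5-fold and more in 50 of 50, while 10 of 9427 unchanged genes were called. For miR155_KO against WT these counts were 27 of 50, 50 of 50 and 8 of 9427.

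Sfpi1 and Pax5 were also tested by exact permutation of the libraries (two-sided, scipy 1.17.1), a family of 6 tests. With 4 libraries against 5 the smallest exact p is 0.0159, and with 5 against 5 it is 0.00794. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the other steps.

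Before the data were examined, 30 gene lists were fixed from textbook knowledge of B cells, the stimuli and the cell types a spleen preparation could hold. They named 640 distinct genes, of which 483 were tested, and 22 lists had at least 5 tested members. The lists covered published miR-155 targets, genes associated with PU.1, genes repressed by Pax5, the plasma cell programme, the unfolded protein response, B cell identity, class switch recombination, responses to IL-4, LPS and interferon, cytokines, chemokines, adhesion, the cell cycle, p53 targets, glycolysis and hypoxia, oxidative phosphorylation, ribosomal proteins, immediate early genes, mitochondrially encoded transcripts, heavy chain constant regions and markers of T cells, macrophages, neutrophils, NK cells, mast cells, erythroid cells, stroma and dendritic cells. Each list was compared with all other tested genes by camera in limma with a preset correlation between genes of 0.01, adjusted over the 22 lists of a comparison, and again with the correlation estimated from the data. No camera call of a list in any comparison held with an estimated correlation, so these calls rest on the preset value. Fry in limma, which tests the members of a list against no change and not against other genes, was run on the same 22 lists. Its adjusted p is given for PU1_KI against WT. Single members are called over all genes, with the count adjusted over the list alone beside it.

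The named genes were set by a rule fixed at the same time. It takes the 8 largest rises and 8 largest falls of each mutant against WT among called genes whose genotype ranges do not overlap and whose mean RPKM is at least 2 in the higher group, and the 5 largest of each sign for miR155_KO against PU1_KI. It adds the 6 genes with the largest smaller change in both mutants, up to 3 called members of each list with the smallest adjusted p, and Sfpi1, Pax5, Prdm1, Irf4, Xbp1, Bach2, Bcl6, constant regions and Ddx3y whatever their result. Some genes that this rule names are not reported here. Immunoglobulin and T cell receptor segments and unnamed or predicted genes were passed over. Any gene outside this rule is marked as chosen after its values were seen. Values of genes with near-identical copies are uncertain, because the authors' counting could have split or shared reads between them. These are Bcl2a1a, Bcl2a1b, Bcl2a1d, Csf2rb2, ribosomal proteins with pseudogenes and the constant region gene Ighg2c. The same holds for overlapping genes on opposite strands.

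For miR-155 seed sites, the longest annotated 3' UTR of each gene was taken from GENCODE M21 (GRCm38) by Ensembl identifier and searched for 8mer and 7mer matches; no coordinate was moved between builds. Genes with a site were compared with genes without a 6mer by the difference in median log2 fold change, against a permutation test of 100000 resamples within 10 bins of UTR length, with 20 other 7mers of the same base composition as controls. Called genes within 10 Mb of the Sfpi1 or Mir155 loci on NCBIM37 were compared with the rest by Fisher's exact test; the miR-155 locus was placed by its neighbour Mrpl39. To see how many calls arise by chance, the libraries of each comparison were regrouped in 100 of the 126 possible ways. A library was marked as far from the others of its genotype where Dixon's ratio was above its 95% critical value. For overlaps of both mutants, unchanged groups were simulated 100 times by shuffling the deviations of all 14 libraries from their genotype means over all groups. Both simulated mutants were compared with the same simulated WT group. The real WT libraries were also split into 2 and 2 in 6 ways.

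Alternatives fixed before the data were examined were pseudocounts of 0.1 and 1, no filter or a filter of 5 RPKM, median-of-ratios scaling, quantile normalization, a fit of only the genotypes compared, array weights, the replicate number as a block, an adjusted p under 0.01, a change of at least 1.5-fold, each library left out in turn, immunoglobulin genes left out with RPKM rescaled, 8mer sites, control 7mers and a distance of 5 Mb. Added after seeing the data were each library left out for the seed sites, and each locus alone for the neighbours. The planned ratio of Ighg1 to Ighm was not run.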

Results

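The series measured polyadenylated RNA of activated mouse B cells in 14 libraries, 4 from WT, 5 from PU1_KI and 5 from miR155_KO mice. The title of the series concerns how miR-155 and its target PU.1 act on Pax5 during terminal differentiation of B cells. PU.1 is an ETS family transcription factor of myeloid and B cells, Pax5 is the factor that maintains B cell identity, and miR-155 is a microRNA induced when B cells are activated. LPS with IL-4 drives B cells to proliferate, to switch antibody class and, in part, to become plasmablasts. Depth was 39.7 ± 3.6 M reads in WT (SD, n = 4), 38.8 ± 5.6 in PU1_KI (n = 5) and 46.4 ± 6.2 in miR155_KO (n = 5). The 3 genotypes separated on the first principal component, which held 66.1% of the variance. On it the WT libraries lay from -18.2 to -15.4, PU1_KI from -13.1 to -9.8 and miR155_KO from 19.8 to 27.7. The library miR155_KO_5 stood apart at 19.8, with the other 4 at 24.2 or above, and WT_1 at -15.4, with the other 3 at -18.1 or below. These n hold for every value below.

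Sfpi1 (ENSMUSG00000002111), the gene of PU.1, was higher in every PU1_KI library than in any WT library. It lies on chromosome 2 from 90922547 to 90955913 on the plus strand of NCBIM37. The WT libraries held 9.73, 12.5, 13.2 and 12.6 RPKM, the PU1_KI libraries 21.1, 22.5, 25.6, 25.96 and 23.3, and the miR155_KO libraries 16.7, 17.1, 15.5, 15.8 and 18.3. The log2 difference from WT was 0.96 in PU1_KI and 0.47 in miR155_KO (exact permutation p = 0.0159 for each, the smallest possible, Benjamini-Hochberg adjusted p = 0.0191). Between the mutants Sfpi1 was lower in miR155_KO by a log2 difference of -0.49 (exact permutation p = 0.00794, adjusted p = 0.0191). In GENCODE M21 (GRCm38) the 3' UTR of Spi1 spans chromosome 2 from 91115392 to 91115756, 365 nt of the plus strand. It holds 1 match to the miR-155 seed, the 8mer AGCATTAA from 91115437 to 91115444, within the sequence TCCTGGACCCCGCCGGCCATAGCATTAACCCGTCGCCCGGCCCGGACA. The loss of miR-155 itself in miR155_KO was not analysed here.

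Pax5 rose in PU1_KI and not in miR155_KO. Its level was 35.8 ± 2.42 RPKM in WT, 43.7 ± 3.70 in PU1_KI and 35.8 ± 0.42 in miR155_KO. The log2 difference from WT was 0.28 in PU1_KI (exact permutation p = 0.0159, adjusted p = 0.0191) and 0.00 in miR155_KO (exact permutation p = 0.889). The mutants differed by -0.28 (exact permutation p = 0.00794, adjusted p = 0.0191), a limma call that ended with quantile normalization, where the difference was -0.08 (limma adjusted p = 0.116). With the same normalization Pax5 was called higher in miR155_KO than in WT, by 0.14 (limma adjusted p = 0.0143).

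Among the other regulators of B cell fate, Irf4, which drives plasma cell differentiation, rose in both mutants. It went from 37.9 ± 1.98 RPKM in WT to 49.5 ± 5.61 in PU1_KI and 60.1 ± 3.45 in miR155_KO (log2 fold change 0.38 ± 0.07 and 0.66 ± 0.07, limma adjusted p = 0.00066 and 2.35e-07). Xbp1, which expands the secretory apparatus, fell from 134 ± 6.78 to 106 ± 10.5 and 107 ± 9.75 RPKM (log2 fold change -0.35 ± 0.08 and -0.32 ± 0.08). Prdm1, the master regulator of plasma cells, stood at 5.86 ± 0.28 RPKM in WT, 4.62 ± 0.79 in PU1_KI and 4.30 ± 0.99 in miR155_KO. It fell in miR155_KO (log2 fold change -0.43 ± 0.12, adjusted p = 0.00525). In PU1_KI its log2 fold change of -0.33 ± 0.12 did not pass (adjusted p = 0.054), although it did with median-of-ratios scaling (-0.41, adjusted p = 0.0136). Bach2, a repressor of plasma cell differentiation, rose in PU1_KI from 4.70 ± 0.18 to 6.29 ± 0.32 RPKM (log2 fold change 0.39 ± 0.06, adjusted p = 3.6e-05). In miR155_KO it stood at 5.04 ± 0.30 (adjusted p = 0.164), with a rise of 0.14 that passed under median-of-ratios scaling (adjusted p = 0.0322). Bcl6, the regulator of germinal centre B cells, fell in both mutants, from 8.56 ± 0.60 to 6.82 ± 0.52 and 4.79 ± 0.19 RPKM. The Y-linked gene Ddx3y was at 10.3, 9.82 and 9.66 RPKM in the 3 genotypes, with no call.

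**Figure D1:**
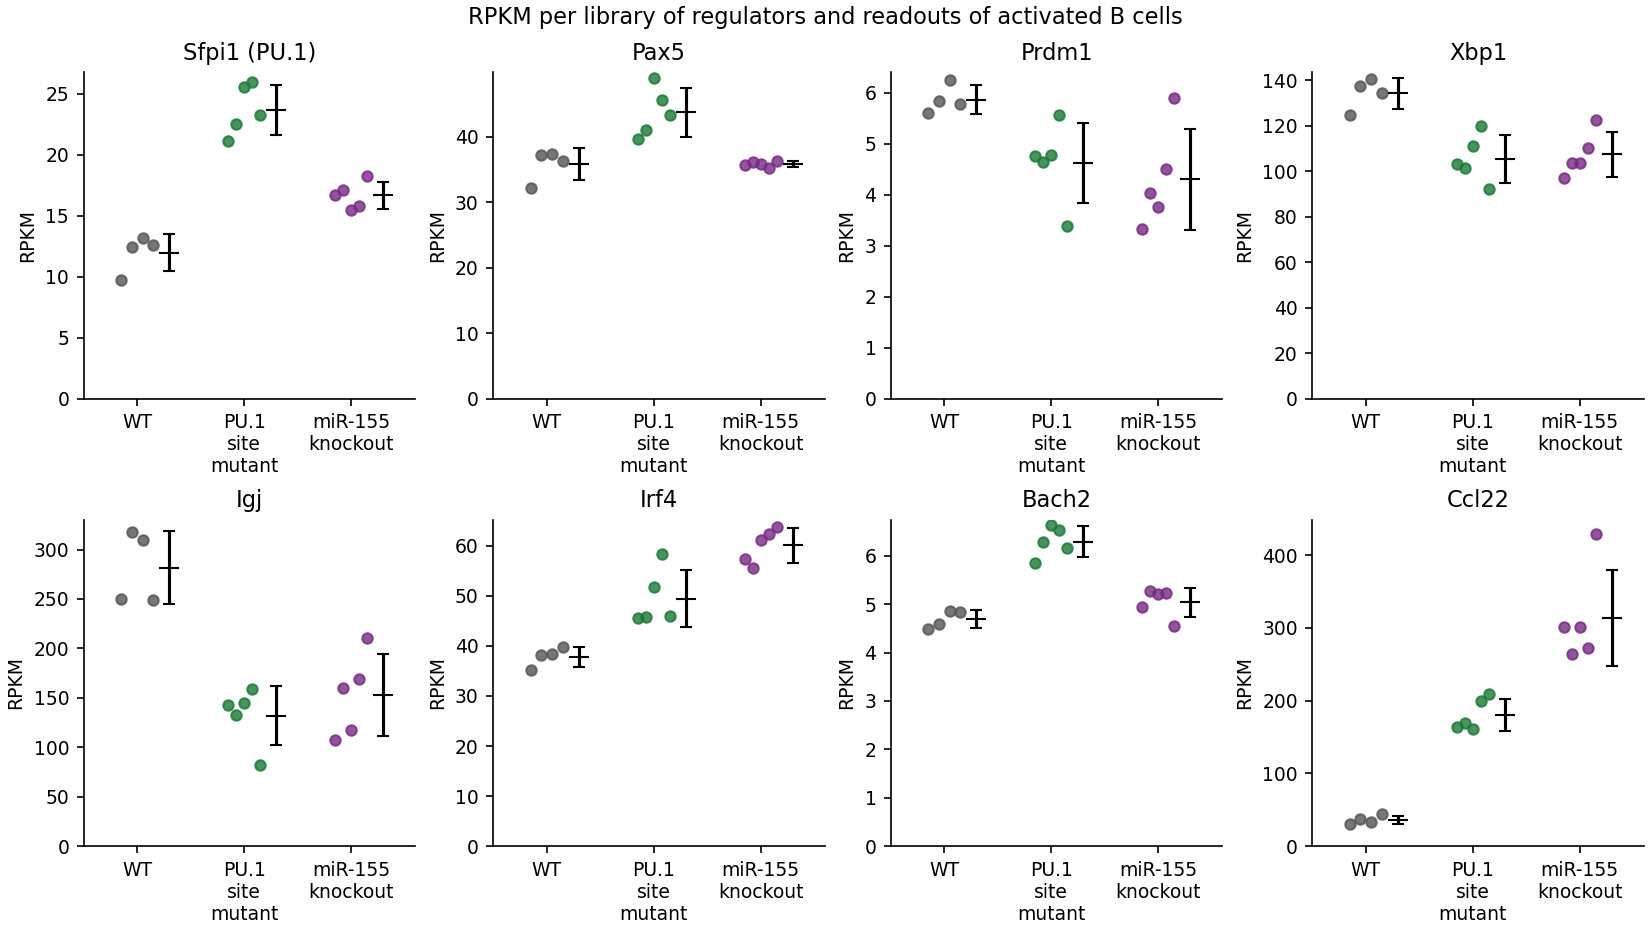
RPKM per library (points) with genotype mean and SD for Sfpi1, Pax5, Prdm1, Xbp1, Igj, Irf4, Bach2 and Ccl22 in WT (n = 4), PU1_KI (n = 5) and miR155_KO (n = 5). Sfpi1 lies between 21.1 and 25.96 RPKM in PU1_KI, above the 15.5 to 18.3 of miR155_KO and the 9.73 to 13.2 of WT.

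The comparison of PU1_KI with WT asks what changes when miR-155 can no longer act on PU.1 while its other targets remain subject to it. The most strongly raised gene was Ccl22, a chemokine that attracts cells bearing Ccr4, from 36.1 ± 5.92 to 181 ± 22.2 RPKM (log2 fold change 2.31 ± 0.13). Tspan33, a tetraspanin of activated B cells, rose from 0.873 ± 0.082 to 5.22 ± 0.71 RPKM (2.05 ± 0.08), and Sema4a, a semaphorin that costimulates T cells, from 2.24 ± 0.32 to 9.35 ± 0.63 (1.85 ± 0.08). Erg, an ETS family transcription factor, fell from 2.01 ± 0.11 to 0.40 ± 0.055 RPKM (-1.48 ± 0.07). Igj, the J chain that joins polymeric antibodies, fell from 282 ± 36.9 to 132 ± 29.6 RPKM (-1.12 ± 0.18, adjusted p = 0.000124).

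Of the 9627 genes tested, 2667 passed in PU1_KI, 2279 higher and 388 lower, and 262 of these changed at least 1.5-fold, 214 higher and 48 lower. The balance of rises and falls depended on scaling. With median-of-ratios scaling 1677 genes were higher and 1518 lower, and with quantile normalization 1520 and 1549. At 1.5-fold or more, 153 were higher and 70 lower with median-of-ratios scaling. The median log2 fold change of all genes was 0.08 as deposited.

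The remaining genes with the largest rises were Wdfy1, an adaptor of Toll-like receptor signalling (log2 fold change 1.64 ± 0.06), Cd300lf, an inhibitory receptor of myeloid cells (1.57 ± 0.07), Car2, a carbonic anhydrase (1.56 ± 0.11), Xkrx (1.46 ± 0.08) and Lrrc25 (1.46 ± 0.08). Their adjusted p values lay between 6.47e-09 for Car2 and 2.51e-13 for Wdfy1. The largest falls after Erg were in AF085738 (-1.33 ± 0.39, adjusted p = 0.0139, or 0.0633 without a filter on low values), P2rx3, an ATP-gated channel (-1.22 ± 0.13), and Egfl7, a secreted factor of endothelium (-1.16 ± 0.12). Next came Cd96, a receptor of T and NK cells (-1.14 ± 0.08), Hemgn, a nuclear protein of blood progenitors (-0.89 ± 0.07), and Sepp1, the selenium transport protein (-0.89 ± 0.08). P2rx3 went the other way in miR155_KO, where it rose from 5.54 ± 0.82 to 11.03 ± 2.41 RPKM (0.92 ± 0.13, adjusted p = 4.57e-06).

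Interferon response genes rose together in PU1_KI. Of 26 measured, 24 rose and 0 fell, or 25 and 0 adjusted over the list alone, with a median log2 fold change of 0.63 (camera adjusted p = 5.49e-19). With an estimated correlation this call was lost (adjusted p = 0.284). Rsad2, an antiviral enzyme, rose from 1.28 ± 0.11 to 3.76 ± 0.27 RPKM (1.26 ± 0.07), Oas2, which senses double-stranded RNA, from 5.05 ± 0.24 to 10.7 ± 0.74 (1.02 ± 0.06), and Oasl2 from 5.97 ± 0.15 to 12.4 ± 1.30 (0.99 ± 0.07).

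Of 28 measured genes of the LPS, Toll-like receptor and NF-kB response, 20 rose and 1 fell in PU1_KI, or 22 and 1 adjusted over the list alone (camera adjusted p = 4.13e-08; adjusted p = 0.595 with an estimated correlation). The antiapoptotic genes Bcl2a1b and Bcl2a1d, near-identical copies with uncertain values, rose by 0.99 ± 0.06 and 0.87 ± 0.07 on the log2 scale, and Socs3, a feedback inhibitor of cytokine signalling, by 1.13 ± 0.10. The IL-4 and STAT6 response had 10 rises and 1 fall among 18 genes, or 12 and 2 adjusted over the list alone (camera adjusted p = 0.00721; adjusted p = 0.595 with an estimated correlation). Besides Ccl22 and Socs3 it held Cish, another feedback inhibitor, which rose from 19.7 ± 1.72 to 29.3 ± 2.45 RPKM. Chemokines and migration genes rose in 9 of 16 cases with 0 falls, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.0147; adjusted p = 0.595 with an estimated correlation). With median-of-ratios scaling 8 rose and 1 fell, and without a filter on low values the call was lost (adjusted p = 0.2). Ccl5 rose from 16.8 ± 4.04 to 45.4 ± 3.60 RPKM and Ccr7, the receptor that guides B cells to T cell zones, from 17.8 ± 1.93 to 32.5 ± 3.0.

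Glycolysis and hypoxia genes were also higher, with 16 rises and 0 falls among 22, or 18 and 0 adjusted over the list alone, and a median log2 fold change of 0.36 (camera adjusted p = 5.42e-07; adjusted p = 0.595 with an estimated correlation), or 14 and 0 with median-of-ratios scaling. Aldoa, a glycolytic enzyme, rose from 286 ± 18.1 to 433 ± 16.2 RPKM (0.60 ± 0.07), Ankrd37, a hypoxia target, from 4.64 ± 0.20 to 9.34 ± 1.00 (0.93 ± 0.10) and Vegfa, the angiogenic growth factor, from 9.44 ± 0.56 to 16.8 ± 1.83 (0.79 ± 0.07).

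PU.1-associated genes rose in 13 of 25 cases and fell in 0, with the same counts adjusted over the list alone (camera adjusted p = 0.000274; adjusted p = 0.595 with an estimated correlation), and 12 rose and 2 fell with quantile normalization. Ncf1, a subunit of the phagocyte oxidase, rose from 106 ± 6.67 to 161 ± 13.9 RPKM (0.59 ± 0.07), Cd68, a lysosomal protein of macrophages, from 6.80 ± 0.48 to 10.9 ± 0.58 (0.64 ± 0.06) and Csf3r, the receptor for G-CSF, from 0.777 ± 0.081 to 1.68 ± 0.23 (0.77 ± 0.07). Beside them, of 20 macrophage markers, 6 of them also in another list, only Cd68, Mpeg1 and Ctsb passed the expression filter, and all 3 rose, while the highest of the others, Apoe, was at 0.989 RPKM in WT and 0.856 in PU1_KI.

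By camera the plasma cell programme lay below the other genes, with 5 rises and 8 falls among 28 genes. Adjusted over the list alone these were 5 and 10 (camera adjusted p = 1.85e-05, or 0.595 with an estimated correlation). Fry gave no call for the list (adjusted p = 0.294). With median-of-ratios scaling 3 rose and 15 fell. Besides Igj it held Eaf2, an elongation factor partner, which fell from 8.58 ± 0.37 to 5.91 ± 0.65 RPKM, and Cd93, a surface receptor of long-lived plasma cells, which rose from 10.6 ± 0.14 to 13.3 ± 1.01. Genes repressed by Pax5, a list that shares members such as Igj, Prdm1 and Xbp1 with the plasma cell programme, had 3 rises and 6 falls among 16. Adjusted over the list alone these were 3 and 7 (camera adjusted p = 0.0183, or 0.595 with an estimated correlation). The call was also lost with median-of-ratios scaling (adjusted p = 0.111), quantile normalization (adjusted p = 0.141) and a filter of 5 RPKM (adjusted p = 0.22). It was lost too with immunoglobulin genes left out and RPKM rescaled (adjusted p = 0.133), a setting that kept 9626 of the 9627 genes. The members with the smallest adjusted p were Il2rb, a shared interleukin receptor chain, which fell from 4.19 ± 0.40 to 2.40 ± 0.20 RPKM, and Lmo2, a transcription cofactor, and Lilrb4, an inhibitory receptor, which rose by 0.71 ± 0.07 and 0.74 ± 0.08 on the log2 scale. B cell identity genes had 14 rises and 2 falls among 33, with the same counts adjusted over the list alone and no call for the list (camera adjusted p = 0.211); with median-of-ratios scaling 12 rose and 4 fell, and without a filter on low values the list was called up (adjusted p = 0.0354). Cd38, an ectoenzyme of NAD metabolism, and Etv6, an ETS family repressor, rose by 0.54 ± 0.07 and 0.47 ± 0.06.

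G1/S and DNA replication genes fell in 7 of 28 cases with 0 rises, the same adjusted over the list alone (camera adjusted p = 3.02e-05; adjusted p = 0.595 with an estimated correlation), and in 16 cases with median-of-ratios scaling. Slbp, the histone mRNA binding protein, fell from 25.0 ± 1.09 to 20.5 ± 1.32 RPKM, and Pola1, a subunit of DNA polymerase alpha, from 8.65 ± 0.47 to 7.18 ± 0.40. Mitochondrially encoded transcripts fell in 3 of 10 cases with 0 rises, the same adjusted over the list alone (camera adjusted p = 0.000815; adjusted p = 0.595 with an estimated correlation), in 6 with median-of-ratios scaling (median -0.28) and in 5 with quantile normalization. These were mt-Cytb, mt-Nd4 and mt-Nd6, of which mt-Cytb and mt-Nd4 lost their calls without a filter on low values (adjusted p = 0.126 and 0.115). Calls were also lost without PU1_KI_2 (adjusted p = 0.0612 for mt-Cytb and 0.0828 for mt-Nd4) or WT_2 (adjusted p = 0.0504 and 0.0589), and for mt-Nd4 without PU1_KI_1 (0.0712), PU1_KI_3 (0.0636), WT_1 (0.0836) or WT_3 (0.0733), while mt-Nd6 fell from 63.0 ± 3.86 to 37.4 ± 10.8 RPKM. Class switch recombination genes had 4 rises and 1 fall among 28, or 3 and 1 adjusted over the list alone; the list median was -0.03 and the mean 0.00, and camera called the list down (adjusted p = 0.029; adjusted p = 0.743 with an estimated correlation). With median-of-ratios scaling 2 rose and 9 fell, and the call was lost with a filter of 5 RPKM (adjusted p = 0.163), without a filter on low values (adjusted p = 0.0995) and without WT_1 (adjusted p = 0.0541). Batf, an AP-1 factor needed for switching, rose from 53.2 ± 6.58 to 80.8 ± 9.37 RPKM, and Xrcc5, an end-joining protein, fell from 4.26 ± 0.42 to 2.67 ± 0.36. The unfolded protein response had 3 rises and 2 falls among 28, or 3 and 1 adjusted over the list alone, and was called down (camera adjusted p = 0.0481; adjusted p = 0.78 with an estimated correlation), although its median and mean were both 0.01; with median-of-ratios scaling its median was -0.08, with 3 rises and 8 falls. This call was lost without a filter on low values (adjusted p = 0.207), without PU1_KI_5 (adjusted p = 0.202), PU1_KI_2 (adjusted p = 0.0695), WT_2 (adjusted p = 0.064) or WT_4 (adjusted p = 0.0517), and with the replicate number as a block (adjusted p = 0.0667). Ddit3, the stress factor Chop, rose from 7.995 ± 0.501 to 11.6 ± 0.92 RPKM, and Dnajb9, a chaperone of the endoplasmic reticulum, fell from 9.07 ± 0.52 to 7.51 ± 0.79.

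Fry gave no call for any list that camera called down in PU1_KI. Its adjusted p was 0.397 for G1/S genes and 0.212 for mitochondrially encoded transcripts. It was 0.938 for Pax5-repressed genes and the unfolded protein response, and 0.999 for class switch recombination. Those calls are relative to all genes, whose median was 0.08. For the other lists camera made no call. Of these, fry called p53 targets (adjusted p = 0.0053), cytokines (0.00874), adhesion (0.0087), B cell identity (0.028) and dendritic cell markers (0.00081). Fry tests against no change, so its calls include the shift of all genes. Beyond that shift the list medians were 0.04 for B cell identity and 0.06 for cytokines and for adhesion. They were 0.11 for p53 targets and 0.35 for dendritic cell markers. Published miR-155 targets had 6 rises and 4 falls among 30, or 8 and 5 adjusted over the list alone (camera adjusted p = 0.254, median 0.01), and with median-of-ratios scaling 5 rises and 10 falls (median -0.08). Besides Sfpi1, Peli1, an E3 ligase of Toll-like receptor signalling, rose from 8.72 ± 0.29 to 12.2 ± 0.55 RPKM and Lpin1, a phosphatidate phosphatase, from 4.13 ± 0.21 to 5.31 ± 0.40. The p53 targets had 9 rises and 1 fall among 23, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.0571), and the list was called up without a filter on low values (adjusted p = 0.00457) and with quantile normalization (adjusted p = 0.0443). Its member Pmaip1, a proapoptotic BH3-only protein, rose from 10.8 ± 0.86 to 22.3 ± 2.11 RPKM. Adhesion and T cell interaction genes had 12 rises and 5 falls among 30, the same adjusted over the list alone (camera adjusted p = 0.438), or 10 and 7 with median-of-ratios scaling. The costimulatory ligand Cd80 rose from 4.54 ± 0.51 to 10.3 ± 0.85 RPKM, Slamf1 from 1.82 ± 0.19 to 4.50 ± 0.27 and Sema7a from 8.32 ± 1.01 to 17.9 ± 2.21. Cytokines and their receptors had 11 rises and 6 falls among 24, the same adjusted over the list alone (camera adjusted p = 0.258), with rises in Il10ra and Csf2rb2. Immediate early genes had 3 rises and 3 falls among 18, the same adjusted over the list alone (camera adjusted p = 0.15), or 2 and 5 with median-of-ratios scaling, and were called down without PU1_KI_1 (adjusted p = 0.0317) or WT_4 (adjusted p = 0.027). Oxidative phosphorylation had 0 rises and 1 fall among 25, and 0 of each adjusted over the list alone (camera adjusted p = 0.0543). Under median-of-ratios scaling it was called down (adjusted p = 0.00875), with 0 rises and 8 falls and a median of -0.06. It was also called down with quantile normalization (0.0189), a filter of 5 RPKM (0.0398) and the replicate number as a block (0.0469). The same held with immunoglobulin genes left out and RPKM rescaled (0.00932), and without PU1_KI_2 (0.0469), PU1_KI_4 (0.0257), WT_1 (0.0263) or WT_3 (0.0328). Ribosomal proteins had 3 rises and 0 falls among 30 and G2/M genes 3 and 0 among 27, both 0 and 0 adjusted over the list alone (camera adjusted p = 0.955 and 0.721). Both were placed down by camera with medians of 0.09 and 0.08, and under median-of-ratios scaling the medians were 0.01 and -0.01 and ribosomal proteins were placed up. Of their members, Rps2 and the mitotic genes Anln and Aurka lost their calls under that scaling (adjusted p = 0.0598, 0.146 and 0.0878). Anln also lost its call without WT_2, WT_4 or PU1_KI_5 (adjusted p = 0.0522 to 0.0765), and Aurka without WT_1, WT_2, WT_3, PU1_KI_3, PU1_KI_4 or PU1_KI_5 (adjusted p = 0.058 to 0.1).

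Markers of other cell types were mostly below the expression filter, which need not mean a low level, since the table held 0.982 ± 0.141 RPKM in WT for Gapdh, an abundant glycolytic enzyme with many near-identical copies. Of 16 T cell markers (1 also in another list) only Thy1 and Cd2 passed it, and in PU1_KI Thy1 fell from 44.9 ± 1.22 to 37.9 ± 3.09 RPKM while Cd2 was not called (adjusted p = 0.659). Of 14 neutrophil markers (1 also in another list) Lcn2 and Csf3r passed, and both rose. Of 12 NK cell markers (2 also in another list) Tyrobp, which rose, and Il2rb, which fell, passed. Of 12 dendritic cell markers (5 also in another list) 5 passed, with 3 rises and 1 fall, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.15), with Flt3, a cytokine receptor of progenitors, rising from 15.8 ± 1.67 to 26.02 ± 2.33 RPKM. Of 14 stromal and endothelial markers, 0 of them in another list, Pecam1, Eng and Vim passed. Vim rose from 44.2 ± 2.88 to 54.5 ± 5.69 RPKM and Eng from 3.99 ± 0.47 to 4.75 ± 0.44, a call lost with quantile normalization (adjusted p = 0.0661), without a filter on low values (adjusted p = 0.0537) and without any of WT_1, WT_4, PU1_KI_3, PU1_KI_4 and PU1_KI_5 (adjusted p from 0.05 without WT_4 to 0.127 without WT_1). None of 13 mast cell and basophil markers or of 14 erythroid and platelet markers passed, with 0 of either in another list. The highest means were 0.38 RPKM for Hdc and 0.51 for Hbb-b2. The constant region gene Ighg2c rose from 3.38 ± 0.93 to 5.40 ± 1.07 RPKM (log2 fold change 0.62 ± 0.14, adjusted p = 0.00281). Its value is uncertain, since near-identical constant region genes can share reads.

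The comparison of miR155_KO with WT asks what changes when miR-155 is lost for all its targets. Aqp9, an aquaglyceroporin, rose most, from 0.122 ± 0.052 to 12.4 ± 1.70 RPKM (log2 fold change 4.37 ± 0.10), followed by Cox6a2, a subunit of cytochrome c oxidase, from 2.94 ± 0.62 to 32.5 ± 4.94 (3.27 ± 0.13), and Nupr1, a stress-induced nuclear protein, from 1.04 ± 0.19 to 13.1 ± 1.38 (3.14 ± 0.10). Lax1, an adaptor that dampens antigen receptor signalling, fell most, from 54.6 ± 3.81 to 9.41 ± 0.83 RPKM (-2.48 ± 0.06). Lrrc32, which presents latent TGF-beta, fell from 5.16 ± 0.34 to 0.605 ± 0.093 RPKM (-2.36 ± 0.08).

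In miR155_KO 6017 of the 9627 genes passed, 2616 higher and 3401 lower, and 1281 of these changed at least 1.5-fold, 729 higher and 552 lower. At this spread between replicates small shifts passed the test. The median log2 fold change of all genes was -0.05, and with median-of-ratios scaling 3278 genes were higher and 3274 lower.

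Further rises among the 8 largest were Ccl22, from 36.1 ± 5.92 to 314 ± 66.7 RPKM (3.09 ± 0.13), and Csf3r, from 0.777 ± 0.081 to 9.81 ± 0.50 (3.01 ± 0.07). They were followed by Irg1, which makes itaconate, from 0.228 ± 0.056 to 4.86 ± 1.12 (2.86 ± 0.11), Tspan33 (2.76 ± 0.08) and Pmaip1, from 10.8 ± 0.86 to 74.9 ± 3.69 (2.75 ± 0.07). The further falls were in Fosb, an AP-1 subunit (-2.35 ± 0.29), Slfn8, a Schlafen family member (-2.31 ± 0.07), Erg (-2.14 ± 0.07), Mrpl39, a mitochondrial ribosomal protein encoded beside miR-155 (-2.08 ± 0.10), the cytokine Tnf, from 7.14 ± 0.85 to 1.37 ± 0.48 RPKM (-2.06 ± 0.12), and Hemgn (-1.97 ± 0.07).

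Published miR-155 targets rose in miR155_KO: of 30 measured, 23 rose and 4 fell, the same adjusted over the list alone, with a median log2 fold change of 0.52 (camera adjusted p = 1.72e-07; adjusted p = 0.756 with an estimated correlation). Jarid2, a cofactor of the Polycomb complex, rose from 4.44 ± 0.20 to 15.1 ± 0.61 RPKM (1.66 ± 0.05), Zfp652 from 1.51 ± 0.03 to 4.37 ± 0.17 (1.28 ± 0.05) and Peli1 from 8.72 ± 0.29 to 16.8 ± 0.57 (0.91 ± 0.05).

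Glycolysis and hypoxia genes fell in 20 of 22 cases and rose in 1, the same adjusted over the list alone, with a median of -0.83 (camera adjusted p = 6.86e-07; adjusted p = 0.756 with an estimated correlation). Pgk1, a glycolytic enzyme, fell from 95.3 ± 6.76 to 39.6 ± 3.21 RPKM (-1.26 ± 0.07) and Slc16a3, which exports lactate, from 5.86 ± 0.97 to 1.24 ± 0.17 (-1.86 ± 0.09). Vegfa was the member that rose, from 9.44 ± 0.56 to 28.6 ± 0.72 RPKM (1.55 ± 0.07). G1/S and DNA replication genes fell in 24 of 28 cases and rose in 2, the same adjusted over the list alone (camera adjusted p = 1.15e-06; adjusted p = 0.81 with an estimated correlation). The replicative helicase subunits Mcm3 and Mcm7 fell by 0.85 ± 0.07 and 0.74 ± 0.07 on the log2 scale and Pcna, the sliding clamp, from 95.8 ± 3.93 to 56.4 ± 5.32 RPKM. G2/M genes had 1 rise and 14 falls among 27, the same adjusted over the list alone (camera adjusted p = 0.0391; adjusted p = 0.824 with an estimated correlation), a call lost with quantile normalization (adjusted p = 0.172), with a filter of 5 RPKM (adjusted p = 0.0603) and without WT_1 (adjusted p = 0.104), miR155_KO_1 (adjusted p = 0.0641) or miR155_KO_2 (adjusted p = 0.0694). Ccnb1, the mitotic cyclin, fell from 14.8 ± 0.53 to 10.9 ± 0.89 RPKM, while Anln, a cytokinesis protein, rose from 3.22 ± 0.20 to 4.65 ± 0.38.

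Of 28 LPS, Toll-like receptor and NF-kB genes, 20 rose and 6 fell, the same adjusted over the list alone (camera adjusted p = 4.31e-05; adjusted p = 0.756 with an estimated correlation). Il6 rose from 3.32 ± 0.30 to 15.3 ± 1.98 RPKM (2.04 ± 0.10) and Bcl2a1b from 75.7 ± 3.95 to 181 ± 4.85 (1.25 ± 0.06), while Tnf fell. Chemokines and migration genes had 10 rises and 3 falls among 16, the same adjusted over the list alone (camera adjusted p = 0.00361; adjusted p = 0.756 with an estimated correlation), with Ccr7 rising from 17.8 ± 1.93 to 58.2 ± 5.21 RPKM and Cxcr4, the receptor that retains plasma cells in bone marrow, from 10.2 ± 0.71 to 27.1 ± 1.32. The p53 targets had 12 rises and 4 falls among 23, or 13 and 4 adjusted over the list alone (camera adjusted p = 0.00481; adjusted p = 0.81 with an estimated correlation). Besides Pmaip1 and Bcl2a1a, Cdkn1a, a cell cycle inhibitor, rose from 11.6 ± 1.36 to 31.1 ± 2.85 RPKM (1.39 ± 0.09).

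Interferon response genes fell in miR155_KO, the opposite of their direction in PU1_KI. Of 26 measured, 4 rose and 14 fell, the same adjusted over the list alone (camera adjusted p = 0.00767; adjusted p = 0.81 with an estimated correlation). Mx1, an antiviral GTPase, fell from 5.16 ± 0.17 to 1.30 ± 0.09 RPKM (-1.65 ± 0.06), Usp18, which removes Isg15 from proteins, from 11.4 ± 0.77 to 3.70 ± 0.29 and Rtp4 from 8.34 ± 0.77 to 3.29 ± 0.15 (-1.22 ± 0.07). Rsad2 and Oasl2 did not pass in miR155_KO, at 1.34 ± 0.11 and 5.90 ± 0.39 RPKM (adjusted p = 0.506 and 0.844).

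**Figure D2:**
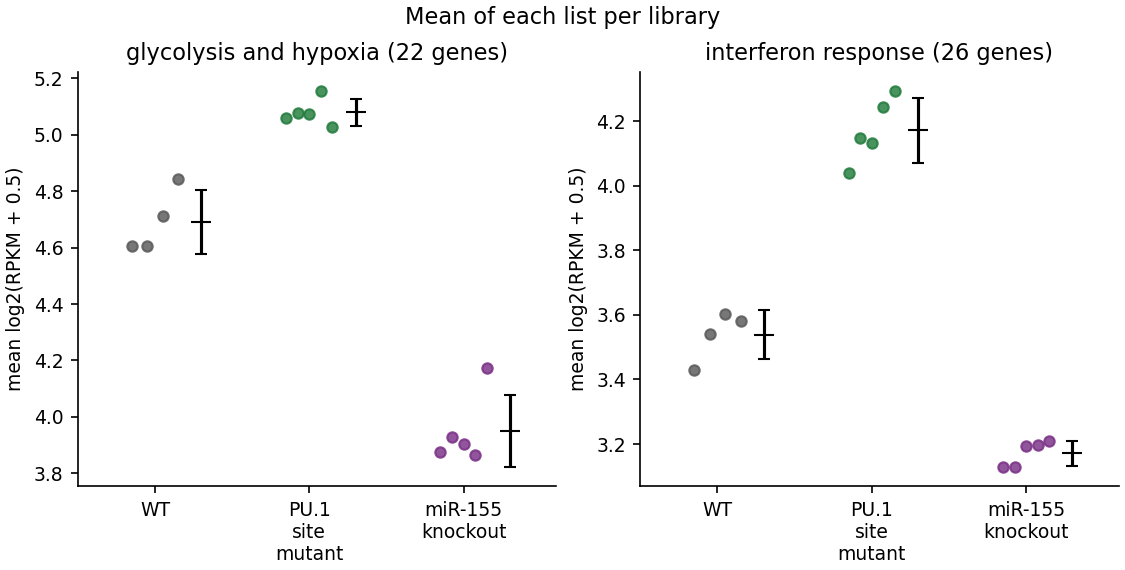
Mean log2(RPKM + 0.5) of the tested members of the glycolysis and hypoxia list and of the interferon response list in each library (points), by genotype, with genotype mean and SD. For glycolysis and hypoxia the WT libraries lie from 4.60 to 4.84, PU1_KI from 5.03 to 5.16 and miR155_KO from 3.87 to 4.17.

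Cytosolic ribosomal proteins fell in 16 of 30 cases and rose in 0, the same adjusted over the list alone, with a median of -0.20 (camera adjusted p = 0.0142; adjusted p = 0.81 with an estimated correlation); the call was lost with a filter of 5 RPKM (adjusted p = 0.0827), and with quantile normalization 21 fell. Immediate early genes fell in 12 of 18 cases and rose in 3, or 13 and 3 adjusted over the list alone (camera adjusted p = 0.0243; adjusted p = 0.81 with an estimated correlation), a call lost with quantile normalization (adjusted p = 0.062) and with the replicate number as a block (adjusted p = 0.0628). Egr1, an early growth response factor, fell from 43.0 ± 2.35 to 19.0 ± 2.09 RPKM and Egr2 from 23.9 ± 2.27 to 14.2 ± 1.43. Mitochondrially encoded transcripts rose in 6 of 10 cases and fell in 2, the same adjusted over the list alone (camera adjusted p = 0.0391, or 0.81 with an estimated correlation). The call was lost with median-of-ratios scaling (adjusted p = 0.0627), quantile normalization (adjusted p = 0.0685) and no filter on low values (adjusted p = 0.0903). It was lost too with immunoglobulin genes left out and RPKM rescaled (adjusted p = 0.0534) and without WT_4 (adjusted p = 0.0567). Transcripts of mt-Nd2 rose from 503 ± 5.10 to 1299 ± 201 RPKM and those of mt-Atp6 from 464 ± 7.39 to 884 ± 103. Oxidative phosphorylation genes encoded in the nucleus had 2 rises and 10 falls among 25, the same adjusted over the list alone (camera adjusted p = 0.296), or 5 and 10 with median-of-ratios scaling. With quantile normalization 9 rose and 8 fell, and camera placed the list up with a median of 0.06. Cycs, cytochrome c, fell from 5.28 ± 0.32 to 3.31 ± 0.38 RPKM.

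**Figure D3:**
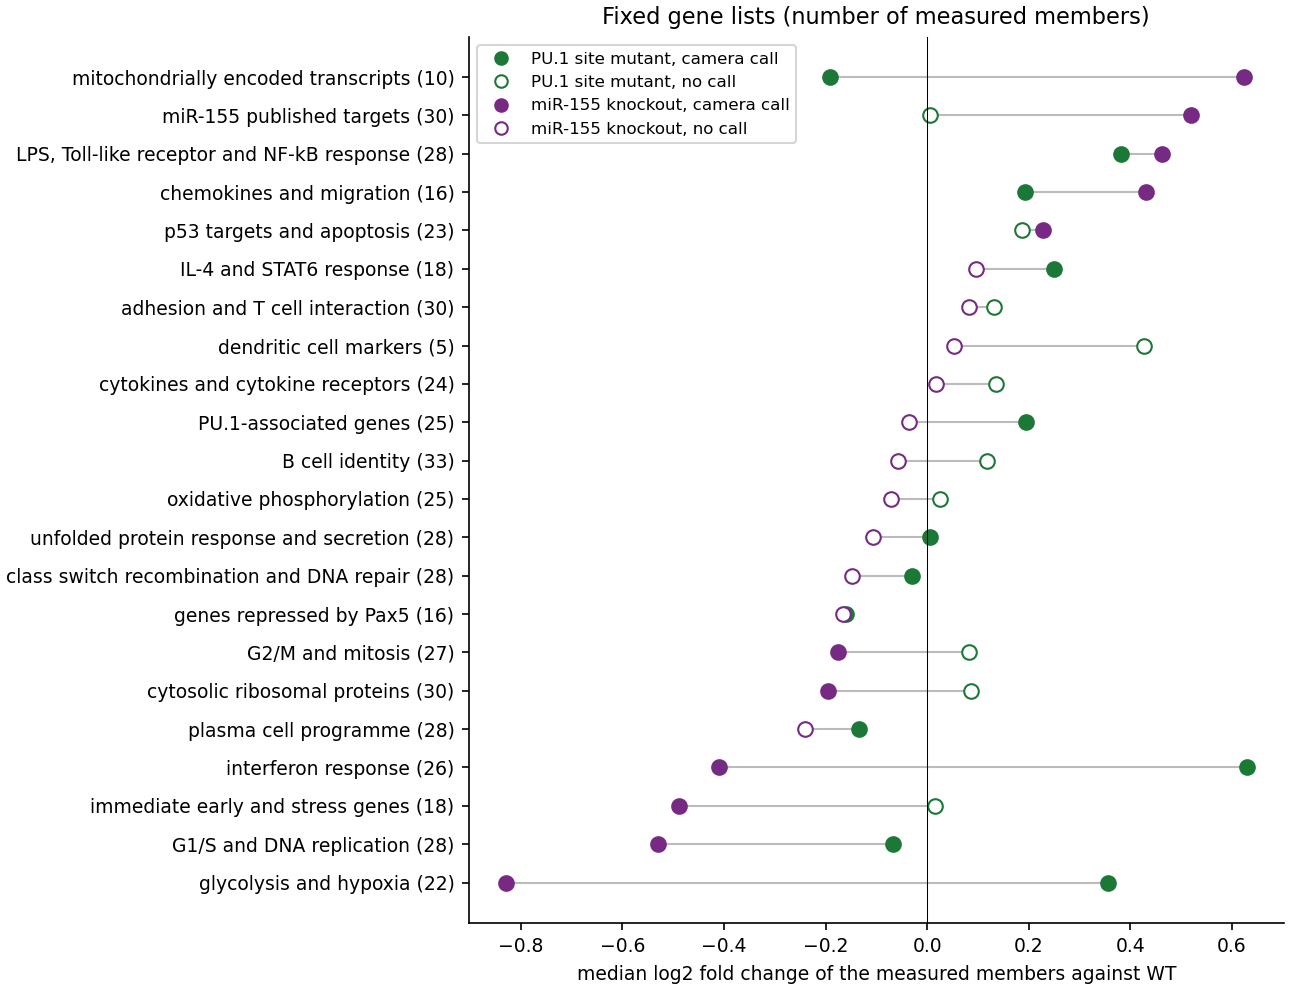
Median log2 fold change of each gene list with at least 5 tested members, PU1_KI against WT and miR155_KO against WT, with calls at a camera adjusted p under 0.05 marked. The interferon list lies at 0.63 and -0.41 and the glycolysis and hypoxia list at 0.36 and -0.83, on opposite sides of 0 in the mutants.

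PU.1-associated genes went both ways in miR155_KO, with 9 rises and 8 falls among 25, or 9 and 9 adjusted over the list alone (camera adjusted p = 0.411). The list median was -0.04 while the mean was 0.24 and camera placed it up; with median-of-ratios scaling the median was 0.01, and with quantile normalization 12 rose and 7 fell. Csf3r rose, as did Tyrobp, an activating adaptor, from 0.587 ± 0.188 to 4.45 ± 0.52 RPKM. Of the neutrophil markers that passed the filter, Lcn2, a siderophore-binding protein, rose with Csf3r, from 0.73 ± 0.176 to 1.52 ± 0.29 RPKM (0.72 ± 0.12). Of the macrophage markers that passed the filter Cd68 and Mpeg1 fell, by 0.39 ± 0.06 and 0.57 ± 0.08 on the log2 scale, and Ctsb, a lysosomal protease, rose by 0.29 ± 0.05.

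The plasma cell programme had 6 rises and 14 falls among 28, the same adjusted over the list alone, and no list call (camera adjusted p = 0.413). Igj fell from 282 ± 36.9 to 153 ± 41.6 RPKM, while Tnfrsf13b, the receptor TACI, rose from 55.8 ± 4.07 to 87.6 ± 2.39. B cell identity genes had 7 rises and 12 falls among 33, the same adjusted over the list alone (camera adjusted p = 0.563), 11 and 12 with median-of-ratios scaling, or 12 and 12 with quantile normalization, where camera placed the list up. Ms4a1, a surface protein of B cells, fell from 144 ± 9.49 to 84.9 ± 4.97 RPKM and Vpreb3 from 56.0 ± 4.17 to 26.5 ± 1.73. Genes repressed by Pax5 had 3 rises and 9 falls among 16, the same adjusted over the list alone (camera adjusted p = 0.483), or 5 and 9 with median-of-ratios scaling. Lilrb4 rose from 0.621 ± 0.076 to 6.95 ± 0.61 RPKM, and Il2rb fell from 4.19 ± 0.40 to 0.766 ± 0.110. Class switch recombination genes had 6 rises and 14 falls among 28, the same adjusted over the list alone (camera adjusted p = 0.176), and the list was called down without a filter on low values (adjusted p = 0.0361). Ung, a uracil glycosylase, fell from 9.25 ± 0.70 to 5.58 ± 0.69 RPKM, and Exosc3, an RNA exosome subunit, from 15.3 ± 0.88 to 9.97 ± 0.68. Ighg2c rose from 3.38 ± 0.93 to 22.6 ± 3.41 RPKM (2.59 ± 0.14, adjusted p = 9.78e-12). This value is uncertain too, since reads of other constant region genes could have been counted in it.

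Among lists with no call in miR155_KO, the unfolded protein response had 7 rises and 8 falls among 28, the same adjusted over the list alone (camera adjusted p = 0.807), with a median of -0.11 and a mean of 0.05. With quantile normalization 9 rose and 4 fell, with a median of -0.02. Ddit3 rose from 7.995 ± 0.501 to 28.3 ± 3.77 RPKM and Ern1, the sensor that activates Xbp1, from 2.09 ± 0.16 to 3.94 ± 0.08. The IL-4 and STAT6 response had 8 rises and 5 falls among 18, or 9 and 5 adjusted over the list alone (camera adjusted p = 0.0664), and was called up with quantile normalization (11 rises and 4 falls, adjusted p = 0.0249). Cytokines and their receptors had 10 rises and 8 falls among 24, or 11 and 8 adjusted over the list alone (camera adjusted p = 0.427). Adhesion and T cell interaction genes had 13 rises and 12 falls among 30, the same adjusted over the list alone (camera adjusted p = 0.243); Cd80 rose from 4.54 ± 0.51 to 16.1 ± 1.19 RPKM and Pdcd1lg2, an inhibitory ligand, fell from 6.10 ± 0.36 to 2.14 ± 0.28. Dendritic cell markers had 2 rises and 1 fall among 5, the same adjusted over the list alone (camera adjusted p = 0.309). Among markers of other cells, Thy1 rose from 44.9 ± 1.22 to 70.6 ± 3.85 RPKM while Cd2 fell from 5.38 ± 0.72 to 3.27 ± 0.58, Pecam1 fell from 6.89 ± 0.34 to 3.38 ± 0.29 and Vim rose from 44.2 ± 2.88 to 80.4 ± 3.73.

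The mutants were compared with each other to test the difference between losing 1 target site and losing the microRNA. Aqp9 (log2 fold change 3.17 ± 0.09), Csf3r (2.25 ± 0.07), Nupr1 (2.24 ± 0.09), Anpep, an aminopeptidase of myeloid cells (2.22 ± 0.07), and mt-Nd3 (2.22 ± 0.09) were the genes most raised in miR155_KO over PU1_KI. Slc16a3 (-2.59 ± 0.09), Slfn8 (-2.46 ± 0.07), Ankrd37 (-2.35 ± 0.09), Usp18 (-2.34 ± 0.06) and Mrpl39 (-2.16 ± 0.09) were the most lowered. Slc16a3 stood at 9.97 ± 0.75 RPKM in PU1_KI and 1.24 ± 0.17 in miR155_KO, and Usp18 at 20.8 ± 1.38 and 3.70 ± 0.29.

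Of 9627 genes 6192 differed between the mutants, 1725 higher and 4467 lower in miR155_KO, and 951 of these by at least 1.5-fold, 413 higher and 538 lower. The median of all genes lay at -0.13 as deposited, and with median-of-ratios scaling 3033 genes were higher and 3013 lower, or 585 and 294 at 1.5-fold or more. Relative to that shift, 9 lists differed by camera. Higher in miR155_KO were published miR-155 targets (22 higher and 5 lower of 30, adjusted p = 9.32e-12; adjusted p = 0.432 with an estimated correlation) and mitochondrially encoded transcripts (7 and 2 of 10, adjusted p = 0.00021; adjusted p = 0.608 with an estimated correlation). Higher too were chemokines and migration genes (8 and 4 of 16, camera adjusted p = 0.00554, or 0.608 with an estimated correlation). So were p53 targets (11 and 5 of 23, camera adjusted p = 0.00598, or 0.854 with an estimated correlation). Lower were the interferon response (1 higher and 24 lower of 26, median -0.88, adjusted p = 2.92e-10; adjusted p = 0.468 with an estimated correlation) and glycolysis and hypoxia (1 and 21 of 22, median -1.20, adjusted p = 3.95e-10; adjusted p = 0.468 with an estimated correlation). Lower too were G1/S genes (2 and 23 of 28, adjusted p = 0.000608), ribosomal proteins (0 and 27 of 30, adjusted p = 0.00527) and immediate early genes (1 and 14 of 18, adjusted p = 0.0481), each with an adjusted p = 0.854 with an estimated correlation. Adjusted over the list alone 28 ribosomal proteins were lower and the counts of the other 8 lists were the same. With median-of-ratios scaling 10 chemokine and migration genes were higher and 3 lower, and 18 ribosomal proteins were lower. Under that scaling G2/M genes were called lower (1 and 14 of 27, camera adjusted p = 0.0399, against 0.0524 as deposited). The unfolded protein response was called higher in miR155_KO (10 and 1 of 28, camera adjusted p = 0.0359). With quantile normalization that list was also called higher (17 and 0, adjusted p = 0.00158), as were the LPS response (adjusted p = 0.0129), the plasma cell programme (adjusted p = 0.0348) and the IL-4 response (adjusted p = 0.0404).

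Both mutants changed many genes in the same direction. The 6 genes with the largest smaller change were Ccl22, Tspan33, Cd300lf, Car2 and Lrrc25, which rose in both, and Erg, which fell in both. Cd300lf went from 2.91 ± 0.33 RPKM in WT to 9.61 ± 0.63 in PU1_KI and 22.01 ± 0.65 in miR155_KO, Car2 from 3.78 ± 0.85 to 12.1 ± 1.90 and 17.1 ± 0.87, and Lrrc25 from 1.87 ± 0.20 to 6.05 ± 0.65 and 10.04 ± 0.69. In all, 1611 genes passed in both mutants in the same direction, 1327 higher and 284 lower, and 321 in opposite directions. With median-of-ratios scaling 1195 genes were higher and 1081 lower in both.

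Because both comparisons use the same WT libraries, part of this overlap arises without any effect. Simulated unchanged groups with a common simulated WT group gave 3.62 same-direction calls on average and at most 361. Few genes pass in such groups, so these counts do not give what shared WT libraries add where many genes change. Independent lists of the observed sizes would share 619 rises and 137 falls. With separate WT libraries for each mutant, 954.8 genes on average were called in the same direction over 6 splits, against 413.8 for independent lists. The covariance of the log2 fold changes was 0.0508 against a simulated 0.00336, a difference of 0.0475, and 0.0479 on average with WT split. The correlation across genes, which are not independent replicates, was 0.537 against a simulated 0.558, and the share of genes with the same sign was 61.1% against 69.2%. Both lay below the simulated means. The simulated groups hold no changed genes, and there the shared WT group alone sets both values. They are therefore no baseline for real changes, and nothing is concluded from them. With WT split, so that the mutants shared no WT library, the correlation was 0.4875 and the same-sign share 60.1% on average.

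**Figure D4:**
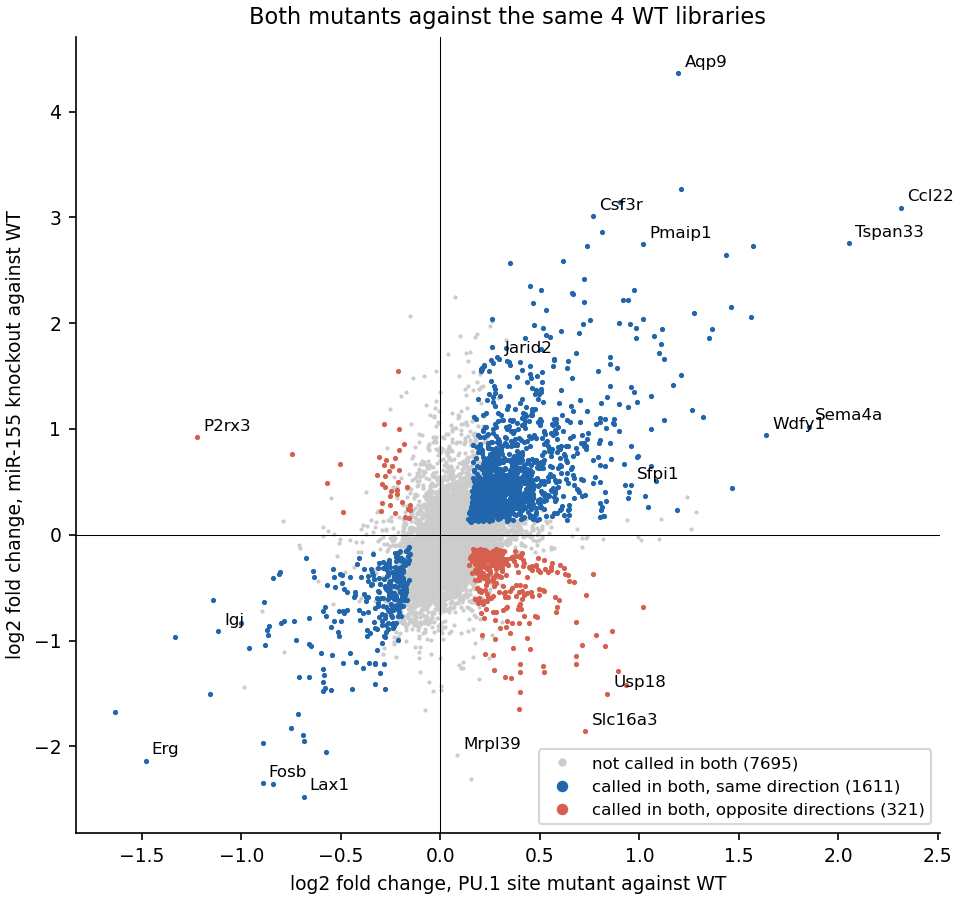
Log2 fold change of each tested gene in PU1_KI against WT (x axis) and in miR155_KO against WT (y axis), with 17 genes labelled. Ccl22 lies at 2.31 and 3.09, Erg at -1.48 and -2.14, and P2rx3 at -1.22 and 0.92.

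Genes with miR-155 seed sites in their 3' UTR were shifted upward in miR155_KO. Of 9414 genes with an annotated 3' UTR, 1285 held a 7mer or 8mer site, 313 of them an 8mer, and 7420 held no 6mer. The median log2 fold change in miR155_KO was 0.10 for genes with a site and -0.08 for genes without one. The difference was 0.17 where UTR length alone gave 0.06 (permutation p = 1e-05, the smallest that 100000 resamples can give). Genes are not independent replicates, so this p does not measure the spread between libraries. For genes with an 8mer, such as Jarid2 among the named genes, the difference was 0.26. Of the 313 genes with an 8mer 168 rose (53.7%) and 43 fell (13.7%), against 1809 (24.4%) and 2849 (38.4%) of genes without a 6mer.

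In PU1_KI the same genes lay slightly lower, with medians of 0.05 with a site and 0.08 without. The difference was -0.04, where UTR length gave 0.00 (permutation p = 1e-05, the smallest possible). The permutation shuffles genes, which are not independent replicates, so its p does not measure the spread between libraries. Beyond UTR length the difference was -0.03, and 1 of 20 control 7mers lay at least as far from 0, between -0.03 and 0.03. Without 1 library, WT_1, the difference was -0.02. In miR155_KO the difference beyond UTR length was 0.12 and none of the 20 control 7mers, from -0.02 to 0.04, lay as far. Between the mutants the difference was 0.20 (permutation p = 1e-05, the smallest possible).

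**Figure D5:**
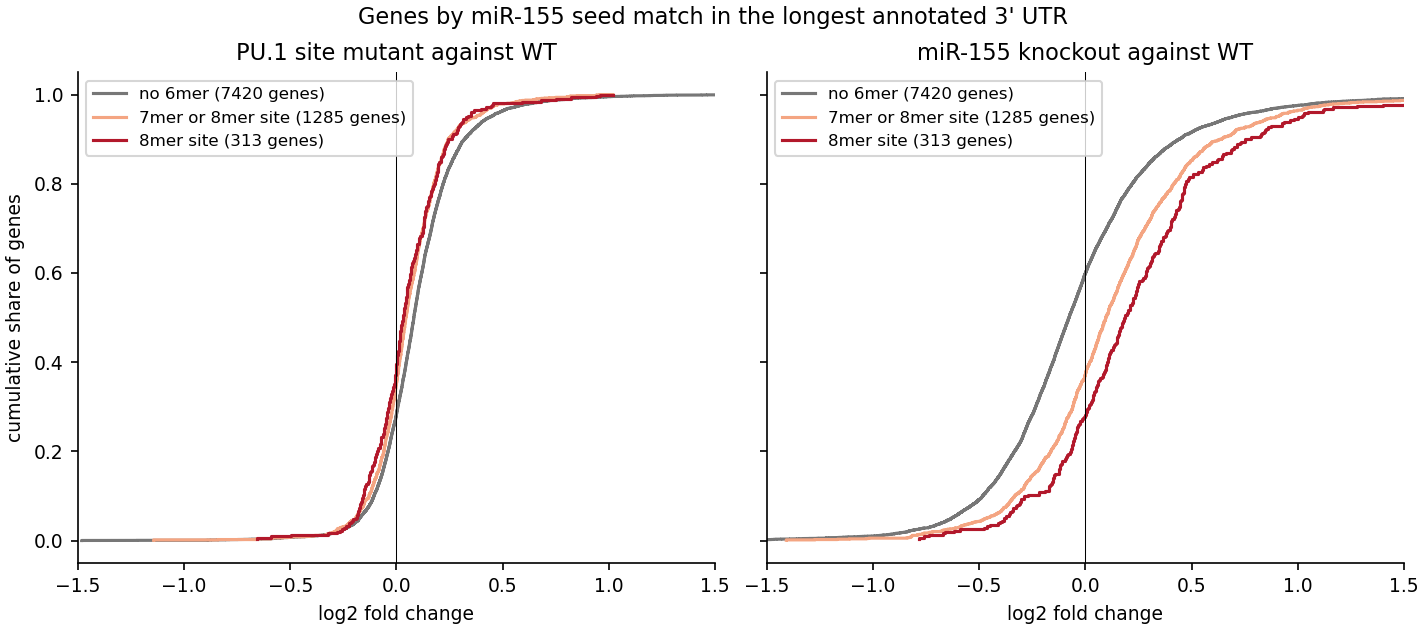
Cumulative share of genes (y axis) by log2 fold change (x axis) for genes with an 8mer, with a 7mer or 8mer site and with no 6mer match to the miR-155 seed, in each mutant against WT. In miR155_KO the medians are 0.19 for genes with an 8mer, 0.10 for genes with any site and -0.08 for genes without a match.

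Genes near the targeted loci were examined because DNA carried along from the targeted strain can change them. Mrpl39, on chromosome 16 from 84717821 to 84735987 (NCBIM37) beside miR-155, fell from 7.51 ± 0.73 RPKM in WT to 1.41 ± 0.30 in miR155_KO, and stood at 7.97 ± 0.65 in PU1_KI (adjusted p = 0.556). Its neighbours Atp5j and Gabpa fell by 0.56 ± 0.06 and 0.29 ± 0.06 on the log2 scale in miR155_KO and App rose by 0.66 ± 0.08; Gabpa and App were named after their values were seen. Within 10 Mb of either locus 67 of 99 genes were called in miR155_KO against 62.4% elsewhere (odds ratio 1.26, Fisher's exact p = 0.299, adjusted p = 0.449), and 20 of 99 in PU1_KI against 27.8% elsewhere (odds ratio 0.658, Fisher's exact p = 0.113, adjusted p = 0.339). Between the mutants 64 of 99 were called (Fisher's exact p = 1.0). Within 5 Mb fewer genes were called in PU1_KI than elsewhere, 5 of 43 (11.6%, odds ratio 0.342, Fisher's exact p = 0.0163, adjusted p = 0.0489).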

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

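Every test in this part that weighs an explanation was chosen only after the result it concerns was seen. That covers the regrouped libraries and the tests on the share of rises in PU1_KI, on glycolysis genes and on myeloid genes. The test on markers of neutrophils and macrophages was tried in 3 forms. The highest increase among abundant transcripts of those cells was 0.026 RPKM, for C1qb, and spoke against them, the highest among Lcn2, Cd68, Mpeg1 and Ctsb was 4.06 and left them open, and the form given last takes all markers with reads. In 33 of 444 groups of libraries, 1 library lay far from the others of its genotype by Dixon's test. Chance puts about 1 in 20 groups there, which makes 22.2, and 13 of the 33 were in the library miR155_KO_5.

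In miR155_KO_5 several genes stood above the other 4 miR155_KO libraries, whose range follows each value. Aldoa was at 274.26 RPKM (216.89 to 230.52), Ccl22 at 429.18 (264.33 to 301.5), Irg1 at 6.8 (3.98 to 4.77), Tnf at 2.22 (1.08 to 1.31), Thy1 at 77.35 (67.61 to 70.14) and Csf2rb2 at 2.24 (1.61 to 1.78). The cell cycle genes Aurka, at 18.59 (16.13 to 16.27), Aurkb, at 29.35 (23.74 to 25.24), Mcm3, at 53.1 (40.8 to 42.93), Mcm7, at 32.22 (25.98 to 27.53), and Pcna, at 65.54 (52.9 to 56.45), were high in it as well. Bcl2a1b was low, at 172.77 (181.23 to 184.34). The mean log2 value of glycolysis and hypoxia genes was 4.173 in this library, against 3.86 to 3.93 in the others.

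In WT_1 the genes Ctsb, at 16.34 RPKM (18.17 to 18.32), Ncf1, at 96.28 (108.69 to 110.49), and Rpl19, at 156.66 (167.23 to 169.13), lay below the other WT libraries, and the first principal component was -15.4 against -18.2 to -18.1. In WT_4 Aurka, at 21.3 (19.43 to 19.72), Cd80, at 5.29 (4.19 to 4.36), and Mcm7, at 49.45 (44.73 to 45.52), lay above them, as did Slfn8 in WT_3, at 9.06 (7.92 to 8.1).

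In PU1_KI_4 Bub3, at 44.45 RPKM (39.19 to 40.67), Ccne2, at 2.27 (2.05 to 2.1), Slbp, at 22.87 (19.81 to 20.12), Thy1, at 43.27 (35.72 to 37.36), and Ung, at 9.47 (7.84 to 8.23), lay above the other PU1_KI libraries. In PU1_KI_5 Mx1, at 8.02 (6.47 to 6.8), and Slfn8, at 10.49 (8.81 to 9.06), lay above them and Eaf2, at 4.8 (6.06 to 6.5), below. In PU1_KI_1 Fosb stood at 7.09 (2.38 to 2.74) and Sema4a at 8.26 (9.37 to 9.79). Among the miR155_KO libraries, mt-Nd6 was at 120.86 in miR155_KO_1 (49.86 to 67.03) and Jarid2 at 16.21 in miR155_KO_3 (14.78 to 14.99).

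Regrouping the libraries of a comparison at random asked whether chance alone calls as many genes. For PU1_KI against WT 2 of 100 groupings, the real one included, called at least 2667 genes; the other called 2857 and placed PU1_KI_1 with the 4 WT libraries. For miR155_KO against WT only 1 of 100, the real one, reached 6017, and the highest other called 5299. Between the mutants it was 1 of 100 as well, with 6192 genes against 4530. Chance alone is an unlikely source of the calls as a whole in all 3 comparisons, at 1 or 2 of the 100 groupings drawn. Regrouping cannot tell genotype from pool or culture day.

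Far more genes rose than fell in PU1_KI, 2279 against 388. Among the genes of the table, a few abundant ones taking fewer of the reads in PU1_KI cannot account for this, since the share of the 10 most abundant differed from WT by 0.04 percentage points. Scaling of the deposited values stays open: among genes called at 1.5-fold or more, the share of rises was 81.7% as deposited and 68.6% of 223 genes with median-of-ratios scaling. The split of 1677 and 1518 over all calls under that scaling follows from its centring and decides nothing. With immunoglobulin genes left out and every library rescaled to the same RPKM sum, 1675 genes were higher and 1465 lower. That setting does not centre on the median gene, so most of the excess over all calls went with the RPKM sums. Whether the sums differ because of the cells or the processing cannot be told from this. Abundant transcripts not used here that took fewer of the reads in PU1_KI stay open, since the RPKM sum was 6.39% above WT with library ranges that overlapped, as does a rise in transcripts per cell, which was not tested.

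Glycolysis and hypoxia genes lay higher in PU1_KI and lower in miR155_KO than in WT. Scaling cannot account for the opposite directions, since with median-of-ratios scaling the list medians were 0.267 and -0.784. Density or handling of cultures that went together with genotype stays open. The smallest gap between genotypes in the mean log2 value per library was 0.18, so no library crossed over, and cultures of a genotype handled together could give the same picture. An effect of the genotype and an effect of shared handling cannot be told apart here.

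Csf3r, Tyrobp, Lilrb4, Anpep, Aqp9, Irg1 and Fcer1g, 7 receptor and enzyme genes known from myeloid cells, were higher in miR155_KO; they form no fixed list and were picked after their values were seen, while the fixed list of PU.1-associated genes had 9 rises and 8 falls. Most other markers argue against reads from neutrophils or macrophages, cells that negative selection is meant to remove. Those cells bring all their abundant transcripts. Yet the upper quartile of the increase among 27 other markers with reads in at least 1 library was 0.02 RPKM, against a median increase of 4.63 in the 7 genes. The cells are not excluded, since an earlier form of the test left them open and a value near 0 need not mean a low level. Of the 27, Ctsb, Lcn2 and Emr1 rose by 10% of that or more (4.06, 0.79 and 0.54 RPKM) and were named after their values were seen, while Cd68 and Mpeg1 fell, Lyz2 stood at 0.096 in WT and 0.086 in miR155_KO, Apoe at 0.989 and 0.827 and Ngp at 0.005 and 0.004. Scaling cannot account for the rises, since the median log2 fold change of the 7 genes was 2.78 with median-of-ratios scaling. Expression by the B cells themselves or by another rare cell type could explain the rises, and was not tested.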

How the results depend on the processing

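The tests chosen only after the results were seen are the seed site comparison without each library and the neighbours of each locus alone. No call for a named gene or gene list turned its direction, but the balance of rises and falls did. In PU1_KI it went from 2279 and 388 to 1520 and 1549 with quantile normalization, and between the mutants at 1.5-fold or more from 413 and 538 to 585 and 294 with median-of-ratios scaling, whose centring on the median gene moves it by construction. For 185 of 203 results for named genes and 30 of 44 for gene lists the side of the threshold held under every alternative run for them. These were the pseudocounts, filters, scalings, immunoglobulin genes left out, the replicate block and each library left out, and for genes also array weights and the fit of only the genotypes compared (183 results); a filter of 5 RPKM covered 171 gene results and 42 list results, and immunoglobulin genes left out 200 gene results. The adjusted p under 0.01 and the 1.5-fold change were run for counts only. Leaving out 1 library at a time gave 1966 (without WT_1) to 3128 (without PU1_KI_1) calls in PU1_KI, 5553 to 6205 in miR155_KO, 5755 to 6471 between the mutants and 1228 to 1769 shared calls. Lists called ranged from 11 to 13 in PU1_KI and from 10 to 12 in miR155_KO. The difference for seed sites ranged from -0.045 to -0.019 (without WT_1) in PU1_KI, from 0.163 to 0.198 in miR155_KO and from 0.184 to 0.218 between the mutants.

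Shared calls numbered 1040 with a filter of 5 RPKM, where fewer genes were tested. With an adjusted p under 0.01, which by construction passes fewer genes, 1605 were called in PU1_KI and 972 shared, and with a change of at least 1.5-fold 262, 1281, 951 and 164 in the 3 comparisons and shared. Control 7mers in place of the seed gave median differences of -0.009, 0.011 and 0.024, as their sequences differ from it. Within 5 Mb the odds ratio in PU1_KI was 0.342; the cause was not tested. Within 5 Mb of miR-155 alone, 10 of 10 genes were called in miR155_KO (Fisher's exact p = 0.0169, adjusted p = 0.0507).

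With the replicate number as a replicate block, 2908, 6326 and 6461 genes were called and 1787 shared, and 12 and 10 lists. The 13 pairs of libraries with the same number had correlations from -0.39 to 0.47, with 7 above 0.1. Of 14 libraries 4 matched best with their own number. The correlations showed no clear pairing by number but cannot exclude it, and what the numbers mark is not given in the sources used here. With the replicate block Aurkb lost its call in PU1_KI (adjusted p = 0.0591, and 0.0582 to 0.146 without WT_1, WT_2, WT_3, PU1_KI_3 or PU1_KI_4), as did the unfolded protein response in PU1_KI (adjusted p = 0.0667) and immediate early genes in miR155_KO (adjusted p = 0.0628). Xbp1 was called higher in miR155_KO than in PU1_KI with median-of-ratios scaling (0.16, adjusted p = 0.0126), and Bst2 lost its call in PU1_KI without WT_1 (0.28, adjusted p = 0.0606). The cause was not tested for any of these.

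The ratio of Ighg1 to Ighm and its alternatives were planned and not run. A change of 1.2-fold was found in 26 of 50 simulated genes for PU1_KI against WT. In that simulation 9427 of 9627 genes were unchanged, so its threshold was stricter than that behind the 2667 real calls. The share of small effects missed in the real comparison cannot be read from it.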

Other observations

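No test in this part was chosen after its result was seen; the genes are those of the naming rule. Atf3, an activating transcription factor, rose in PU1_KI from 5.73 ± 0.40 to 7.78 ± 0.62 RPKM and stood at 5.36 ± 0.27 in miR155_KO. Ier3, an early survival gene, rose in both, from 1.19 ± 0.14 to 2.58 ± 0.55 and 2.61 ± 0.48. Dusp1, a phosphatase of MAP kinases, fell in both, from 7.46 ± 1.02 to 5.34 ± 1.04 and 3.18 ± 0.43. Hsph1, a heat shock protein, and Cd69, an activation marker, fell only in miR155_KO, from 14.1 ± 0.86 to 7.86 ± 0.93 and from 32.5 ± 0.94 to 20.5 ± 2.39. Atf4, the factor of the integrated stress response, rose from 87.7 ± 3.38 to 102 ± 7.05 in PU1_KI and 125 ± 3.26 in miR155_KO. Trp53inp1, a p53 target, fell to 13.3 ± 0.48 in PU1_KI and rose to 25.01 ± 1.63 in miR155_KO, from 16.7 ± 0.53 in WT.

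Dendritic cell markers did not differ between the mutants as a list, with 2 higher and 2 lower of 5 in miR155_KO (camera adjusted p = 0.735). Flt3, a cytokine receptor, rose in both, from 15.8 ± 1.67 to 26.02 ± 2.33 and 22.9 ± 2.33 RPKM. Cst3, a protease inhibitor, rose in PU1_KI from 24.1 ± 1.34 to 32.7 ± 1.78 RPKM and stood at 24.6 ± 1.54 in miR155_KO. Zbtb46, a transcription factor of dendritic cells, rose in miR155_KO from 2.34 ± 0.15 to 4.62 ± 0.29 and stood at 2.67 ± 0.27 in PU1_KI. Bst2, an interferon-induced membrane protein, rose from 74.4 ± 16.6 to 98.6 ± 9.90 in PU1_KI and fell to 52.4 ± 6.42 in miR155_KO. Il10ra, an interleukin receptor, rose in both, from 8.23 ± 0.63 to 13.9 ± 1.26 and 10.8 ± 0.78.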
